A study of Bacillus subtilis subsp. natto with 7 samples.

How the data were processed

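RNA from colonies of *Bacillus subtilis* natto, the strain group of the Japanese fermented soybean food, was compared on 7 spotted DNA microarrays with 2 colours. Per the labels' protocols, cells were spotted on LB medium solidified with agar, grown overnight and harvested from the plate, and the RNA was copied into aminoallyl cDNA and coupled to Cy3 or Cy5. Arrays 1 to 4 set the wild type on 0.7% agar against the wild type on 1.5% agar. Arrays 5 to 7 set RNA labelled spo0A against wild type RNA, both from 0.7% agar. Spo0A is the response regulator that starts sporulation and matrix production. Cy5 carried the 0.7% agar RNA on array 1 and the 1.5% agar RNA on arrays 2 to 4. Cy5 carried the RNA labelled spo0A on array 6 and the wild type RNA on arrays 5 and 7. The design text speaks of 4 biological replicates in the agar comparison and 3 in the other, while the extract protocol speaks of 3 replicate cultures, so whether all 4 agar arrays came from separate cultures was left open. The fits treated every array as an independent replicate, and p-values hold only as far as that is so. Whether one wild type RNA served both comparisons was not given in the sources used here.

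The spot intensities were deposited as one file per array and, per the file headers, hold for each channel a raw brightness, a local background and net values made from them. Channel A was Cy3 and channel B was Cy5, per the labels. The scanner and the quantification software were not given in the sources used here. Each array held 8358 spots in 36 grids, with 4106 gene probes spotted 2 times each and 146 spots of 60 probes whose names start with EX and whose nature was not given. Spots with a raw intensity of 0 in both channels, 304 to 501 on an array, were read as not measured and left out. The authors also deposited a value table with one log ratio per probe and array, whose scale, centring and direction were worked out from the spot files. On bright genes its values followed the spot ratios with a correlation of 0.975 to 0.987 in size and 0.676 to 0.686 of their log2 spread, close to 0.693, the natural log of 2, so the authors' values were read as natural log ratios. The sign of the correlation turned with the dyes so that the authors' table gives 1.5% over 0.7% agar and spo0A over wild type. Its column medians were −0.081, 0.025, 0.14, −0.046, −0.026, 0.025 and −0.019 for arrays 1 to 7. The normalization behind it was not given in the sources used here. It was used only as an alternative.

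The raw intensities were corrected for background with normexp and an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by a loess curve over intensity with a span of 0.3 and 4 iterations, in limma 3.58.1 under R 4.3.3. The EX spots entered normexp, had no weight in the loess and stayed out of every test. The 2 spots of a gene were averaged. Ratios were then given as 0.7% over 1.5% agar and as spo0A over wild type. One linear model with moderated variances (limma lmFit and eBayes) was fitted to all 7 arrays, with a term for each comparison and 1 dye term shared by both, because the dye orientations were unbalanced and neither comparison alone kept more than 2 residual degrees of freedom with a dye term. A gene needed values on at least 3 agar arrays or 2 spo0A arrays. This left 4061 genes in the agar comparison and 4031 in the spo0A comparison. P-values were adjusted over the genes tested by the Benjamini-Hochberg method with a threshold of 0.05, and a gene is called higher or lower only past it. Standard errors are those of the moderated fit, and n counts the arrays of the comparison. The residual variance was pooled over all 7 arrays, so the standard error of one comparison also carries the scatter of the other's arrays. Through the shared dye term a fitted ratio also depends on the arrays of the other comparison. In this fit array 1 had a leverage of 0.647, as had array 6, each being the only array of its dye orientation in its comparison. With each comparison fitted on its own arrays and a dye term, both had a leverage of 1.

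Gene lists were fixed before the data were examined: 30 pathways and regulons were tested as sets, and a list of regulators was described gene by gene. Of 586 list entries 575 were found on the array. Set tests used camera in limma with a preset correlation between genes of 0.01 on the 3710 genes measured on all 7 arrays, adjusted over the 30 lists, and again with an estimated correlation. No list of either comparison passed with the estimated correlation, where the smallest adjusted p was 0.31 in the agar comparison and 0.22 in the spo0A comparison. Fry, a rotation test of whether the genes of a list move one way on balance, was an alternative. The relation between the comparisons was measured with each comparison fitted on its own arrays and its own dye term, by Pearson's r and Spearman's rho across genes and by Fisher's exact test, two-sided, of shared calls. The genes named in the text were set by a rule written before the data were examined. The rule took, per comparison, the 10 largest changes in each direction among genes past the threshold with 1 sign on every array. It added the representatives of each list, 1 called gene with the largest change per list, and spo0A, abrB, sinI and slrR. Genes named outside the rule are said to be so.

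Probes carry locus tags. Of the 4106 gene probes 4038 matched the RefSeq gene table of assembly ASM904v1 of a related laboratory strain of the species, which was used only for names and for which genes neighbour each other. The other 68 and those without a symbol keep their tag. A symbol that the table gives to more than 1 locus was not used, which left epsK out of its list, and 27 list genes were looked up under the table's newer symbol. The position of each probe within its gene was not given.

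The analysis was tested on simulated arrays with known changes and the same design. In the agar comparison, over 4061 genes, 50% of the genes changed by 1 on the log2 scale and 87% of those changed by 2 were recovered, with 2.14% false calls. In the spo0A comparison, over 4031 genes, the shares were 38.4% and 87.9%, with 4.58% false calls. The simulation gave every array equal noise, which the real arrays did not have. The shares and false calls therefore describe the simulated arrays, and those of the real arrays were not measured. The number of arrays limits the precision of every value.

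Alternatives fixed before the data were examined were no background subtraction, a smaller normexp offset, median centring, loess within each grid, scaling between arrays, leaving out dim probes, no dye term, each comparison on its own arrays with and without a dye term, an intensity trend with a robust prior, the authors' values, stricter thresholds, other set tests, and leaving out each array in turn. After the data were seen, 3 more were added: leaving out spots on a high local background, leaving out the grids of array 1 whose median log2 ratio was over 0.5 in size, and array weights. Loess within each grid was also added for the lists and the relation. A gene counted as well above background where its net intensity exceeded 2 robust standard deviations of the local background. No called gene was below this on every array in the channel of either group, so no change is given as a bound. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.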

Results

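Transcript ratios of *Bacillus subtilis* natto colonies grown overnight on agar plates were measured on 7 arrays with 2 colours. The series concerns sliding, the passive spreading of a colony over a surface. Arrays 1 to 4 compared the wild type on soft agar (0.7%) with the wild type on firm agar (1.5%), and arrays 5 to 7 compared RNA labelled spo0A with wild type RNA on 0.7% agar. The median raw intensity lay 1.46 to 8.67 times above the median local background in Cy3 and 1.55 to 4.30 times in Cy5. The lowest values were those of arrays 3, 6 and 7, with 1.71, 2.12 and 1.46 in Cy3. The 2 spots of a gene gave log2 ratios that correlated with r of 0.939 to 0.980 across genes.

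The 3 spo0A arrays resembled each other, with r of 0.80 to 0.90 across genes. Among the agar arrays, arrays 2 and 3 correlated at 0.82, array 4 correlated at 0.44 and 0.38 with them, and array 1 correlated at 0.0015, 0.018 and 0.12 with arrays 2, 3 and 4. On array 1, 54.1% of the variance of the log2 ratio lay between grids, against 1.03% to 5.27% on the other arrays, and 19.9% of its measured Cy5 spots were at or below their background. In 9 of its 36 grids the median ratio was over 0.5 in size. These 9 grids are called the shifted grids here, and they hold 883 of the 4106 gene probes. The 4061 and 4031 genes tested in the agar and spo0A comparisons were spread over all grids.

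**Figure D1:**
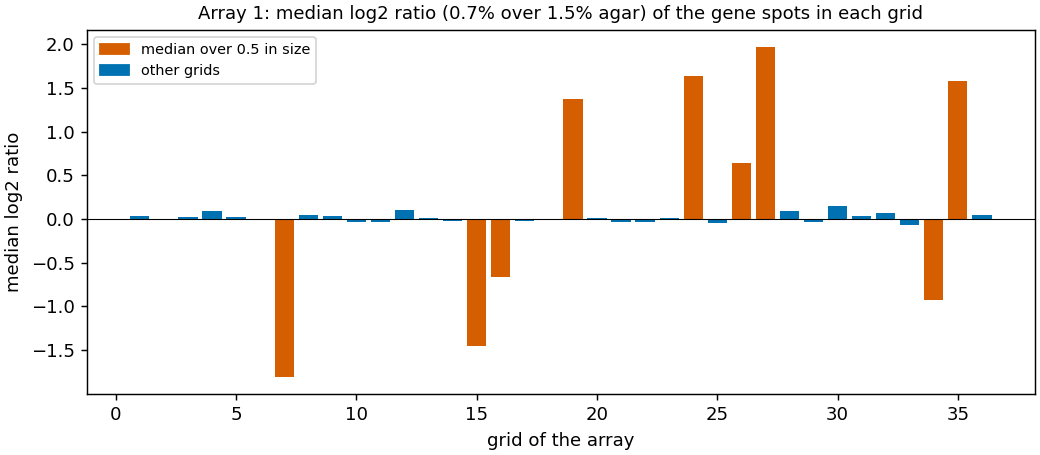
Median normalized log2 ratio (0.7% over 1.5% agar, vertical axis) of the gene spots in each of the 36 grids of array 1 (horizontal axis). Orange bars mark the 9 grids with a median over 0.5 in size, which run from −1.81 in grid 7 to 1.97 in grid 27, while the other grids lie between −0.07 and 0.15.

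The first comparison asked which wild type transcripts differed between soft and firm agar. Ratios are given as 0.7% over 1.5% agar, the opposite of the authors' table. On soft agar the transcripts of gbsA and gbsB, whose enzymes make the osmoprotectant glycine betaine from choline, were lower by log2 −3.33 ± 0.48 (SE, n = 4 arrays; limma with Benjamini-Hochberg, adjusted p = 0.0484) and −3.26 ± 0.50 (adjusted p = 0.0499). Also lower were sboX, in the operon of the bacteriocin subtilosin, at −2.72 ± 0.17 (adjusted p = 0.00848), and acoB, a subunit of acetoin dehydrogenase, at −2.31 ± 0.24 (adjusted p = 0.0448). Genes of the App oligopeptide transporter were higher, with appB at 1.79 ± 0.25, appD at 1.33 ± 0.18 and BSU11380, which lies between appF and appB, at 2.01 ± 0.29 (adjusted p = 0.0484 each). The branched-chain amino acid dehydrogenase gene bcd was higher at 1.24 ± 0.17, the inositol dehydrogenase gene iolX at 1.17 ± 0.18 and rpmB, for a protein of the large ribosomal subunit, at 1.01 ± 0.14 (adjusted p = 0.0484 each). The spore coat assembly gene spoVIF was lower at −1.97 ± 0.21, and BSU10190, which lies between yhfC and yhfE, was lower at −2.44 ± 0.35 (adjusted p = 0.0484 each). Each of these 12 genes had 1 sign on all 4 arrays and probes outside the shifted grids of array 1. The spread between the agar arrays could be wider than the pooled standard error conveys. For gbsA the 4 arrays ran from −5.43 to −1.46, with a standard deviation of 1.72.

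A further 10 named genes past the threshold had their probes in the shifted grids of array 1. Higher among them were rocD and rocE of arginine catabolism, at 1.66 ± 0.25 and 1.48 ± 0.18, and yqxG, at 1.15 ± 0.14. Lower among them were the extracellular protease gene bpr at −2.80 ± 0.28, etfA and fadR of the fatty acid degradation operon at −2.67 ± 0.35 and −2.38 ± 0.36, the sporulation gene refZ at −2.53 ± 0.38, yqgW at −2.34 ± 0.35, flgN of the flagellar regulon at −1.60 ± 0.24 and the purine gene purA at −1.57 ± 0.22. The adjusted p was 0.0448 for bpr and 0.0484 for the other 9. With the shifted grids left out these genes had 3 agar arrays, and bpr stayed past the threshold at −2.05 while the other 9 did not, none of them with a turned sign. The fitted ratio was then 1.30 for rocE, −2.62 for refZ, 1.09 for rocD, −1.88 for etfA, −1.83 for fadR, −1.41 for yqgW, −1.37 for flgN, −1.27 for purA and 0.19 for yqxG. Fewer arrays and the shift of the grids were not told apart as reasons for the lost calls. The ratio of yqxG was 2.11 on array 1 and 0.02 to 0.32 on the other agar arrays, and its fitted ratio turned to −0.03 with loess within each grid.

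**Figure D2:**
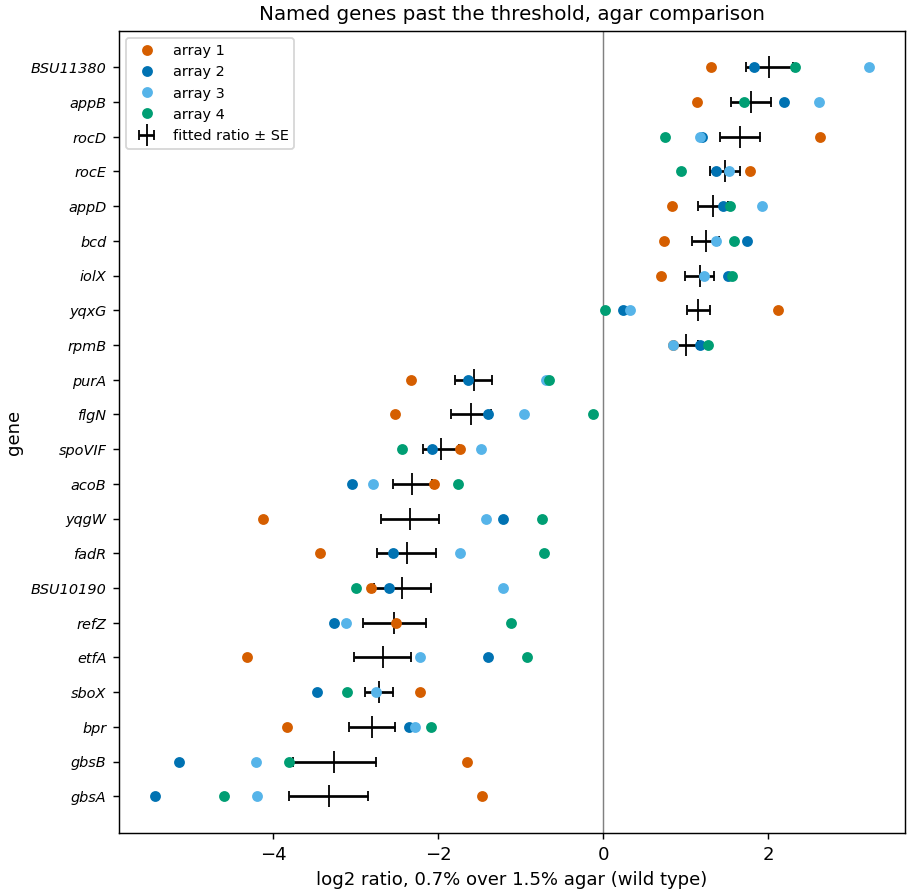
Log2 ratio (0.7% over 1.5% agar, horizontal axis) of the 22 named genes past the threshold in the agar comparison (vertical axis). Coloured points are arrays 1 to 4 and black bars the fitted ratio ± SE, from −3.33 for gbsA to 2.01 for BSU11380, and array 1 lies far from the other arrays for yqxG and bpr.

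Of 4061 genes, 10 were higher and 28 lower on soft agar, and 36 of the 38 changed at least 2-fold on the fitted scale. A ratio of 1 sign on all 4 arrays was found for 9 of the higher and 27 of the lower genes. The unadjusted p was under 0.05 for 871 genes. Of the 38 genes 23 lay in the shifted grids of array 1, where 8.18 would lie by chance, and with those grids left out 30 genes were called, 16 of them among the 38. Leaving out array 1, 3, 5 or 7 left 0 calls in limma, with 913, 625, 674 and 653 genes at an unadjusted p under 0.05. Leaving out array 2 left 1 call, leaving out array 4 left 3, and leaving out array 6 gave 438.

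Among the fixed lists, 7 passed camera as higher on soft agar and 8 as lower. With an estimated correlation camera passed 0 lists, and 2 had an unadjusted p under 0.05, while fry passed 3. The median ratio of many lists, though not of acetoin and acetate use, was near 0 on arrays 1 and 4 and came mainly from arrays 2 and 3. The gene list plot shows this for arginine synthesis, with medians of 0.02, −4.48, −1.53 and 0.00 on arrays 1 to 4. Other exceptions included surfactin, with medians of 0.853 and 0.841 on arrays 1 and 4, and arginine catabolism, at 0.715 on array 4. Ribosomal proteins had a median of 0.492 on array 4 and −0.141 on array 2. Arrays 2 and 3 also had a higher median local background in Cy3, 570.8 and 740.9, against 124 to 214.4 on the other arrays. Whether they shared a culture or a processing batch was not given. Lists that rest mainly on them may therefore not rest on 2 independent replicates. Without array 6, which enters through the shared dye term, 6 lists passed.

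Surfactin genes, for the lipopeptide that wets the surface around a colony, leaned higher on soft agar. All 5 measured members had positive ratios, with srfAA at 1.43 ± 0.36 (adjusted p = 0.12) and srfAC at 1.54 ± 0.39 (adjusted p = 0.117). None passed over all genes, 4 passed adjusted over the list alone, and the list passed camera (median 1.43, adjusted p = 0.004, and adjusted p = 0.55 with an estimated correlation). The eps operon for the matrix exopolysaccharide had 0 of 14 members past the threshold and 2 higher adjusted over the list alone, epsH at 2.85 and epsM at 1.97. Its list passed camera as higher (median 0.24, adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation), although epsA stood at −1.14 ± 0.67. Without the shifted grids its adjusted p was 0.15, without array 3 it was 0.057 and without array 6 it was 0.13. The fitted ratios of the 4 matrix protein genes went both ways, with bslA, the hydrophobic coat protein, at 1.75 ± 0.38 (adjusted p = 0.0973) and the fibre protein gene tasA at −1.85 ± 0.70 (adjusted p = 0.208). None passed over all genes, 1 was higher (bslA) and 2 lower (sipW and tasA) adjusted over the list alone, and camera did not pass (median −0.38, adjusted p = 0.79). The members epsM and sipW are named here after their values were seen. The representative epsE stood at 1.315 ± 0.43 (adjusted p = 0.165). The probes of epsA, epsE, epsH, tapA and tasA lie in the shifted grids of array 1, while that of bslA does not. On array 1 tasA read −4.67, against −0.45 to −0.05 on the other agar arrays. There epsA read −3.98, against 0.11 to 0.75 on the others. Over the 4 agar arrays epsH ran from −0.05 to 4.66 and epsE from −0.055 to 2.14, so neither kept 1 sign.

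The arginine catabolism list passed camera as higher, with 2 of 8 members past the threshold (rocD and rocE), 5 adjusted over the list alone and a median of 0.95 (camera adjusted p = 0.00074, and adjusted p = 0.31 with an estimated correlation). Both called members lie in the shifted grids of array 1, while rocA stood at 1.00 ± 0.32 (adjusted p = 0.164). Branched-chain amino acid synthesis passed camera as higher with 0 of 11 members called over all genes, while adjusted over the list alone 6 were higher and 1 lower (median 0.63, adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation). Its gene ilvB stood at 1.05 ± 0.34, and the list's call was lost without array 6 (adjusted p = 0.091). Glycolysis and the citric acid cycle passed as higher with 0 of 9 and 0 of 13 members called, and 1 and 2 adjusted over the list alone (medians 0.64 and 0.46, adjusted p = 0.01 and 0.0091, and adjusted p = 0.55 each with an estimated correlation). The glyceraldehyde phosphate dehydrogenase gene gapA stood at 1.38 ± 0.52 and the citrate synthase gene citZ at 0.46 ± 0.17. The glycolysis call was lost without array 3 or 6 (adjusted p = 0.057 and 0.054) and the citric acid cycle call without array 6 (adjusted p = 0.091), with loess within each grid (adjusted p = 0.11) and with the authors' values (adjusted p = 0.28). Of 52 ribosomal protein genes 1 was called, rpmB, and adjusted over the list alone 1 was higher and 1 lower. That list passed as higher (median 0.16, adjusted p = 0.018, and adjusted p = 0.7 with an estimated correlation), and not without array 4 or 6 (adjusted p = 0.3 and 0.098), with loess within each grid (adjusted p = 0.37) or with the authors' values (adjusted p = 0.17).

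Sporulation lists leaned lower on soft agar. For the early genes, 11 of 14 ratios were negative, 0 were past the threshold over all genes and 5 were lower adjusted over the list alone (median −0.54, camera adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation). Their members spoIIAA and spoIIE stood at −0.61 ± 0.17 and −1.27 ± 0.52 (adjusted p = 0.136 and 0.231). For later sporulation 40 of 43 ratios were negative with 0 members past either adjustment (median −0.46, camera adjusted p = 0.00011, and adjusted p = 0.58 with an estimated correlation). Its list medians were −0.05, −1.33, −0.69 and −0.05 on arrays 1 to 4. In the spore coat list 2 of 34 members were lower, spoVIF and, named after its value was seen, cotY at −1.40 ± 0.18. Adjusted over the list alone 3 were lower (median −0.22, camera adjusted p = 0.0046, and adjusted p = 0.55 with an estimated correlation). Without array 6 the early sporulation and spore coat calls were lost (adjusted p = 0.13 and 0.084).

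The osmotic stress list passed camera as lower, with gbsA and gbsB past the threshold among 17 members and 6 lower adjusted over the list alone (median −0.51, camera adjusted p = 0.00015, and adjusted p = 0.31 with an estimated correlation). Purine synthesis had all 13 ratios below 0, with purA called over all genes and adjusted over the list alone (median −0.95, camera adjusted p = 0.00018, and adjusted p = 0.55 with an estimated correlation). Arginine synthesis had all 9 ratios below 0 and no member past either adjustment, with argG at −1.54 ± 0.56 (median −1.44, camera adjusted p = 0.037, and adjusted p = 0.71 with an estimated correlation). Its camera call was lost without array 2, 3 or 6 (adjusted p = 0.088, 0.056 and 0.19), with the shifted grids left out (adjusted p = 0.055) and with the authors' values (adjusted p = 0.069). Of the acetoin and acetate genes acoB was called among 9 members, with 5 lower and 2 higher adjusted over the list alone (median −1.21, camera adjusted p = 0.045, and adjusted p = 0.55 with an estimated correlation). The acetyl-CoA synthetase gene acsA stood at 0.56 ± 0.18, and the list's call was lost without array 3, 5 or 6 (adjusted p = 0.057, 0.051 and 0.12), with median centring (adjusted p = 0.087) and with loess within each grid (adjusted p = 0.17). The medians of this list were −1.75, −0.33, −0.22 and −0.13 on arrays 1 to 4, while acoB lay between −3.05 and −1.76 and acoA between −4.18 and −1.18 on these arrays. Without array 1 the list still passed as lower (adjusted p = 0.033). All 6 autolysin genes had negative ratios, with 0 called over all genes and 3 lower adjusted over the list alone, among them lytC at −0.59 ± 0.19 (median −0.44, camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation), and the call was lost with the shifted grids left out (adjusted p = 0.095).

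The 15 other lists did not pass camera in the agar comparison. Flagellum and chemotaxis had flgN lower among 52 members, over all genes and adjusted over the list alone, and a median and mean of 0.00 with a test leaning down (adjusted p = 0.79), and its flagellin gene hag stood at −0.28 ± 0.13. Extracellular proteases had bpr lower among 8, and 2 lower adjusted over the list alone (adjusted p = 0.35). Heat shock had 0 of 14 called and 2 lower adjusted over the list alone (adjusted p = 0.4), and competence 0 of 20 and 1 lower adjusted over the list alone (adjusted p = 0.38). No member passed either adjustment among the other lists. These were poly-gamma-glutamate, the slime polymer of natto (5 members, adjusted p = 0.4), antibiotic synthesis (33, 0.47), phosphate starvation (19, 0.12), potassium transport (9, 0.4), general stress (26, 0.59), oxygen limitation (23, 0.79), pyrimidine synthesis (10, 0.43) and iron acquisition (23, 0.4), which passed as higher without array 1 (adjusted p = 0.049). Cannibalism (10 members, adjusted p = 0.66) and the PBSX prophage (30 members, adjusted p = 0.66) had medians of −0.02 and −0.02 and means of 0.02 and 0.02. Phosphate starvation passed as lower with no dye term and with median centring (adjusted p = 0.049 and 0.037), and the PBSX prophage as higher with the authors' values (adjusted p = 0.048). Of the 30 regulators measured none passed over all genes or adjusted over the list alone. Among them spo0A stood at −0.63 ± 0.25 (adjusted p = 0.217), abrB at 0.45 ± 0.22 (adjusted p = 0.289), sinI at −0.50 ± 0.24 (adjusted p = 0.285) and slrR at 0.19 ± 0.20 (adjusted p = 0.573).

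**Figure D3:**
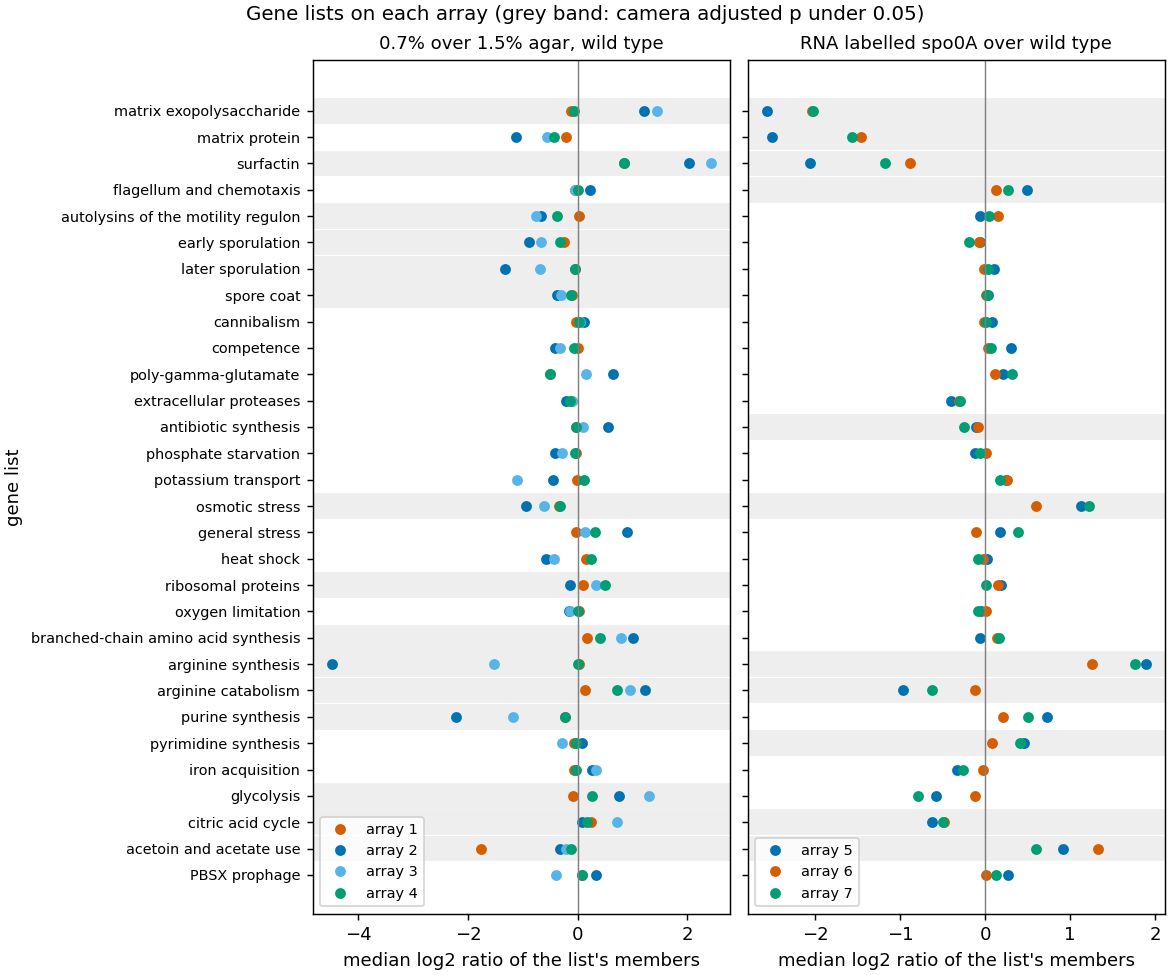
Median log2 ratio of each fixed gene list (horizontal axis) on each array, for 0.7% over 1.5% agar (left) and RNA labelled spo0A over wild type (right); coloured points are arrays and grey bands mark the 15 and 11 lists past camera with the preset correlation. Arrays 1 and 4 lie near 0 for many lists where arrays 2 and 3 do not.

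The second comparison asked which transcripts differed between RNA labelled spo0A and wild type RNA on soft agar. The spo0A gene itself was not lower in RNA labelled spo0A. Its probe read higher by log2 1.28 ± 0.27 (SE, n = 3 arrays; adjusted p = 0.051), at 1.09 to 1.31 on arrays 5 to 7. The standard deviation of its ratio was 0.113 over arrays 5 to 7 and 0.717 over arrays 1 to 4. The standard error pools both, so the missed threshold partly reflects scatter among the agar arrays. The labels do not say how the mutant was made or where the probe lies, and a probe outside the deleted part checks nothing, so the RNA is named by its label throughout. The transcript of abrB, the transition-state regulator that Spo0A represses, was higher in RNA labelled spo0A, at 2.21 ± 0.24 (adjusted p = 0.0102) and 1.86 to 2.55 on the 3 arrays.

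In RNA labelled spo0A the acetoin dehydrogenase operon had the largest increases. The gene acoB stood at 5.10 ± 0.26, a 34.2-fold difference (adjusted p = 0.00113), acoC at 4.92 ± 0.47 (adjusted p = 0.00822), and acoL and acoA at 4.88 ± 0.53 and 4.83 ± 0.54 (adjusted p = 0.0102 each). The glycine betaine genes gbsA and gbsB followed at 4.04 ± 0.53 and 3.40 ± 0.55 (adjusted p = 0.0151 and 0.0254). Also higher were the membrane protein gene nfeDA at 3.47 ± 0.18 (adjusted p = 0.00113), degQ, which promotes phosphorylation of the regulator DegU, at 3.39 ± 0.51 (adjusted p = 0.0222), the cell envelope stress sigma factor gene sigW at 3.09 ± 0.34 (adjusted p = 0.0102) and yuaI at 3.08 ± 0.25 (adjusted p = 0.00524). The ratios of gbsA and gbsB were 2.03 and 1.70 on array 7, below those of arrays 5 and 6.

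The largest decrease was that of aprE, for the extracellular protease subtilisin, at −5.01 ± 0.54 or 32.2-fold (adjusted p = 0.0102). It was followed by bslA, for the hydrophobic coat protein of the colony surface, at −4.04 ± 0.42 (adjusted p = 0.0102). The neighbouring genes yvdA and yvdB fell by log2 −3.24 ± 0.50 and −3.00 ± 0.39 (adjusted p = 0.0222 and 0.0151). Lower too were yraI at −2.96 ± 0.40, the chitosanase gene csn at −2.85 ± 0.33, the esterase gene pnbA at −2.54 ± 0.27, the bacilysin gene bacF at −2.52 ± 0.36 and yhcZ at −2.43 ± 0.15, with adjusted p = 0.0154, 0.0108, 0.0102, 0.0204 and 0.00197. The gene with the tag BSU34260, which lies between epsL and epsJ, stood at −2.37 ± 0.35 (adjusted p = 0.0205).

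**Figure D4:**
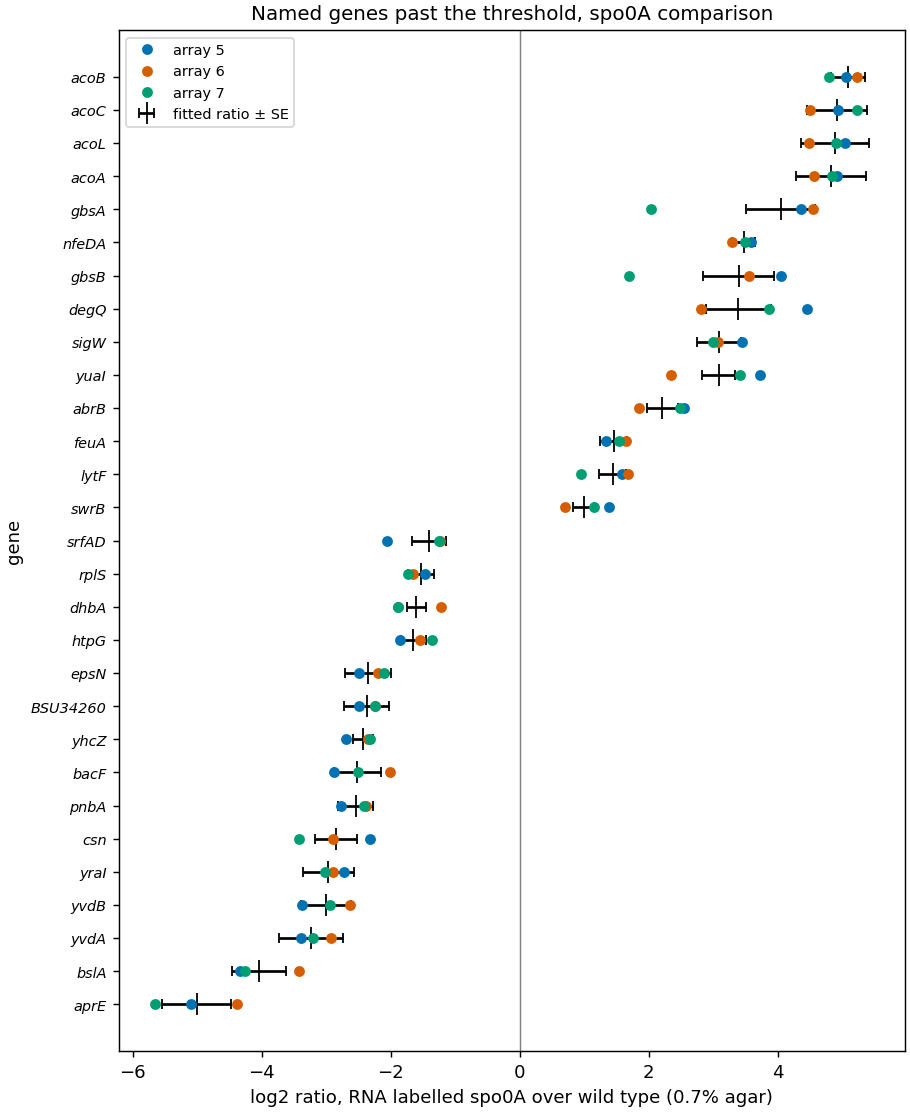
Log2 ratio of RNA labelled spo0A over wild type on 0.7% agar (horizontal axis) for the 29 named genes past the threshold (vertical axis). Coloured points are arrays 5 to 7 and black bars the fitted ratio ± SE, from −5.01 for aprE to 5.10 for acoB, and all points of a gene lie on 1 side of 0.

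Of 4031 genes, 109 were higher and 88 lower in RNA labelled spo0A, 145 of the 197 by at least 2-fold, and the unadjusted p was under 0.05 for 742. A ratio of 1 sign on all 3 arrays was found for 108 of the higher and all 88 of the lower genes. The exception was glnP, named after its values were seen. It was measured on arrays 5 and 7 only, at 0.03 and 0.00, and its fitted ratio of 2.58 came from the shared dye term, which for this gene rested on array 1, at 4.88. Leaving out array 5 or array 7 left 4 calls each, leaving out array 3 gave 118 and leaving out array 6 gave 419. Fitted on its own 3 arrays with a dye term, the comparison gave 1160 calls, 196 of them among the 197.

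Of the fixed lists 5 passed camera as higher in RNA labelled spo0A and 6 as lower. With an estimated correlation camera passed 0, and 4 had an unadjusted p under 0.05, while fry passed 4. The eps operon and the matrix protein list passed camera as lower. For the eps operon 10 of 10 measured ratios were negative, 3 were past the threshold over all genes and all 10 adjusted over the list alone (median −2.21, camera adjusted p = 4.2e-09, and adjusted p = 0.3 with an estimated correlation). The called genes were epsN at −2.35 ± 0.36 (adjusted p = 0.0222) and, named after their values were seen, epsB at −2.29 ± 0.17 and epsC at −1.57 ± 0.20. The representatives epsA and epsH stood at −2.85 ± 0.73 and −2.44 ± 0.63 (adjusted p = 0.0871 each), and epsE read 3.99-fold lower (adjusted p = 0.0698), all with probes in the shifted grids of array 1. On arrays 5 to 7 epsA read −2.76 to −2.07 and epsH −3.10 to −2.45. Their fitted ratios lie outside these ranges, because the shared dye term also draws on the agar arrays. Of the 4 matrix protein genes bslA was called, and 2 were lower adjusted over the list alone (mean −2.02, camera adjusted p = 0.011, and adjusted p = 0.3 with an estimated correlation). Of the others, tasA stood at −3.25 ± 0.77 (adjusted p = 0.0698) and tapA at −0.04 ± 0.64. The surfactin list passed camera as lower with 5 of 5 negative ratios, srfAD called at −1.40 ± 0.26 (adjusted p = 0.038) and 4 adjusted over the list alone (median −1.40, camera adjusted p = 0.0022, and adjusted p = 0.38 with an estimated correlation).

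Antibiotic synthesis passed as lower with 2 of 31 members called, bacF and, named after its value was seen, bacE at −1.76 ± 0.32, and 3 adjusted over the list alone. Both belong to bacilysin synthesis, and the list's median was −0.07 (camera adjusted p = 0.0047, and adjusted p = 0.65 with an estimated correlation). Arginine catabolism passed as lower with 8 of 8 negative ratios and none past either adjustment, rocD standing at −0.93 ± 0.27 (median −0.67, camera adjusted p = 0.0049, and adjusted p = 0.3 with an estimated correlation). Its call was lost with loess within each grid and with the authors' values (adjusted p = 0.052 and 0.28). The citric acid cycle passed as lower with 0 of 13 called and 2 adjusted over the list alone, citZ standing at −0.70 ± 0.18 (median −0.60, camera adjusted p = 0.037, and adjusted p = 0.62 with an estimated correlation). Its call was lost without array 1, 5 or 7 (adjusted p = 0.057, 0.059 and 0.061) and with the shifted grids left out (adjusted p = 0.085). It was also lost with no dye term, median centring, loess within each grid and the authors' values (adjusted p = 0.057, 0.09, 0.11 and 0.32), so the list passed in 4 of 12 alternatives.

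Acetoin and acetate genes passed as higher with 5 of 9 members called over all genes and adjusted over the list alone (median 1.01, camera adjusted p = 0.00016, and adjusted p = 0.34 with an estimated correlation). They were acoA, acoB, acoC, acoL and, named after its value was seen, their activator gene acoR at 1.01 ± 0.16, while acsA stood at −0.49 ± 0.20. Osmotic stress genes passed as higher with 6 of 17 called and 11 adjusted over the list alone (median 1.06, camera adjusted p = 1e-06, and adjusted p = 0.22 with an estimated correlation). Beside gbsA and gbsB these included the compatible solute transporter gene opuCC at 1.46 ± 0.19, named after its value was seen. Flagellum and chemotaxis had 51 of 52 ratios above 0, of small size, and passed as higher (median 0.31, camera adjusted p = 8e-07, and adjusted p = 0.34 with an estimated correlation). Its 2 called genes, also called over the list alone, were the swarming gene swrB at 0.99 ± 0.17 (adjusted p = 0.0299) and, named after its value was seen, cheD at 0.87 ± 0.15. The flagellin gene hag stood at 0.31 ± 0.15 (adjusted p = 0.338). Arginine synthesis had 9 of 9 ratios above 0 and none past either adjustment, argG standing at 1.84 ± 0.62 (median 1.81, camera adjusted p = 0.0061, and adjusted p = 0.65 with an estimated correlation). Pyrimidine synthesis had 10 of 10 above 0 and none past either adjustment (median 0.26, camera adjusted p = 0.026, and adjusted p = 0.63 with an estimated correlation), and its call was lost without array 1, 5 or 7 (adjusted p = 0.069, 0.059 and 0.072).

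The sporulation lists did not pass in this comparison. Early sporulation had 0 of 13 members called and 1 higher adjusted over the list alone, spo0A itself, with a median of −0.11, a mean of 0.04 and a test leaning down (adjusted p = 0.86). Later sporulation had 0 of 43 and spore coat 0 of 33 past either adjustment (adjusted p = 0.72 and 0.63). Among genes known to need Spo0A for their transcription, spoIIAA stood at −0.26 ± 0.18 (adjusted p = 0.593), spoIIE at 0.30 ± 0.57 (adjusted p = 0.921) and spoIIGA at 0.11 ± 0.17 (adjusted p = 0.897).

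Several other lists held called genes without passing camera. Iron acquisition had dhbA of the siderophore bacillibactin lower at −1.60 ± 0.14 (adjusted p = 0.00645) and feuA, for the binding protein that takes up iron-loaded bacillibactin, higher at 1.46 ± 0.21 (adjusted p = 0.0202). Adjusted over that list alone 5 were higher and 3 lower of 21 (camera adjusted p = 0.63). Extracellular proteases had aprE lower and, named after its value was seen, wprA higher at 0.87 ± 0.16 among 8, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.16). Ribosomal proteins had 1 higher and 2 lower of 51, rplS at −1.53 ± 0.20 (adjusted p = 0.0151) and, named after their values were seen, rplK at −0.76 and rpmI at 0.77, and 11 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.72). Heat shock had htpG lower at −1.65 ± 0.19 (adjusted p = 0.011) and, named after its value was seen, clpX lower at −1.16 ± 0.22 among 14, and 3 lower adjusted over the list alone (camera adjusted p = 0.46), and autolysins had lytF higher at 1.45 ± 0.21 (adjusted p = 0.0205) among 6 on both adjustments (camera adjusted p = 0.18). Of the 30 regulators abrB, degQ and, named after their values were seen, comP, rapA and phrA were higher, and adjusted over the list alone 6 were higher and 2 lower. Of the representatives sinI stood at −0.01 ± 0.27 and slrR at −0.75 ± 0.21 (adjusted p = 0.997 and 0.114).

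In the remaining lists no member passed either adjustment and camera did not pass. These were purine synthesis (13 members, adjusted p = 0.053), competence (20, 0.066), the PBSX prophage (30, 0.092), glycolysis (9, 0.093), potassium transport (8, 0.16), cannibalism (11, 0.63) and poly-gamma-glutamate (5, 0.63). Of the cannibalism genes skfA, sdpC, skfB and skfH were not well above background on any array in RNA labelled spo0A, nor sdpA in wild type RNA. For these genes, of which skfB, skfH and sdpA are named after their values were seen, a lack of change cannot be read from the result. For phosphate starvation (19, 0.95), general stress (25, 0.88), oxygen limitation (23, 0.68) and branched-chain amino acid synthesis (11, 0.95) the signs of median, mean and test differed, with medians of 0.01, −0.02, 0.02 and −0.08. Purine synthesis passed as higher without array 2, 4 or 6 (adjusted p = 0.0096, 0.022 and 0.021), and glycolysis passed as lower without array 6 (adjusted p = 0.03).

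The last question was how the responses to soft agar and to the spo0A label relate. Across genes they opposed each other on balance. Of 9 genes past the threshold in both comparisons, 8 moved in opposite directions: acoB, gbsA, gbsB and yjbC were lower on soft agar and higher in RNA labelled spo0A, and iolX, appD, appB and BSU11380 were higher on soft agar and lower in RNA labelled spo0A. The ninth was glnP, whose ratios of 2.31 and 2.58 both rested on array 1. Of these, yjbC and glnP are named after their values were seen. As gbsA and gbsB are neighbours, and appD, appB and BSU11380 lie in one stretch, the 8 genes are not 8 separate loci.

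With each comparison fitted on its own arrays and dye term, a fit in which arrays 1 and 6 each had a leverage of 1, Pearson's r across 3988 genes was −0.254 and Spearman's rho −0.262, where genes are not independent replicates. All 12 pairs of an agar array and a spo0A array correlated below 0, from −0.39 to −0.08. Both comparisons hold wild type RNA from soft agar on opposite sides of the ratio, so RNA shared between them would by itself give a negative value, and whether it was shared is not given. In 100 simulations with shared RNA and no effect the mean r was −0.352 (−0.396 to −0.295), further from 0 than the observed r, and the mean covariance −0.0319 (−0.0368 to −0.0258), and the observed covariance was −0.0984. These simulations gave every array equal noise, split evenly between the channels, and left out the grid shift of array 1. Their ranges are therefore no limit on what shared RNA could give on the real arrays. Of 3894 genes tested in both separate fits, 52 were lower on soft agar and higher in RNA labelled spo0A, against 26.6 for independent lists (Fisher's exact test, two-sided, p = 7.3e-07, adjusted over the 4 pairings 2.9e-06). By the same exact test 31 were higher on soft agar and lower in RNA labelled spo0A, against 21.2 (p = 0.022, adjusted 0.022), 45 were lower in both, against 25.9 (p = 0.00011, adjusted 0.00022), and 11 were higher in both, against 21.7 (p = 0.0088, adjusted 0.012). These counts rest on array 1, which had no residual in that fit, and without a dye term limma called 0 agar genes on the same arrays, with 589 at an unadjusted p under 0.05, so no overlap was left to test. Part of the excess in the opposing pairings may come from shared RNA, which could not be split here. Shared RNA would not by itself give the excess of genes lower in both. With the shifted grids of array 1 left out r was −0.384.

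**Figure D5:**
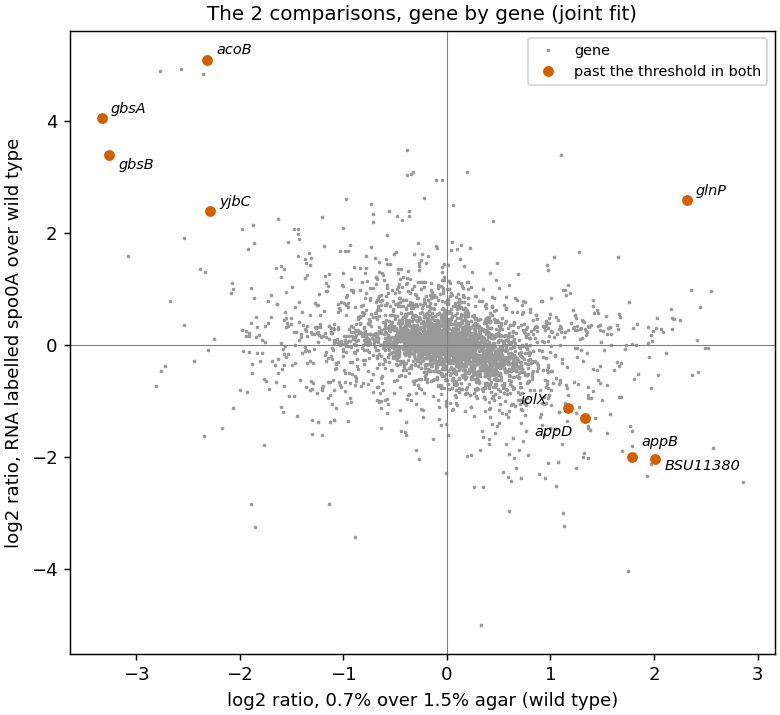
Log2 ratio of each gene on 0.7% over 1.5% agar (horizontal axis) against its log2 ratio in RNA labelled spo0A over wild type (vertical axis), both from the fit of all 7 arrays. Orange points are the 9 genes past the threshold in both, of which 8 lie in the opposing quadrants and glnP does not.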

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

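Every test weighed in this part was chosen only after the result was seen. Among the 90 genes named for the agar comparison that were measured on 4 arrays, 5 had 1 array far from the other 3, where chance gives about 4.5. On array 1 these were yqxG at 2.11 (others 0.02 to 0.32), the protease gene bpr at −3.84 (others −2.35 to −2.08), epsA at −3.98 (others 0.11 to 0.75) and tasA at −4.67 (others −0.45 to −0.05). On array 3 the pyrimidine gene pyrE stood at −0.38 (others 0.00 to 0.02).

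Array 1 was unlike the other agar arrays, and all 4 genes set apart on it lay in its shifted grids. Signal bias in part of the slide is a candidate explanation: outside the shifted grids array 1 correlated with array 4 at r = 0.52, no lower than arrays 2 and 3 did with array 4. That explanation was not enough against arrays 2 and 3, with which array 1 still correlated at no more than 0.18 outside those grids. Dye labels turned round on array 1 were argued against by the lowest of its 3 correlations there, 0.15, where a turned array would lie below 0. A difference between the cultures stays open as untested. Array 1 was also the only agar array of its dye orientation. Dye effects that differ between genes were not tested as a reason and stay open too.

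The spo0A probe was not lower in RNA labelled spo0A. Strain labels exchanged on all 3 arrays were argued against by abrB, which Spo0A represses and which was higher at 2.21. A mutation that leaves the probed part of the gene in place stays open, as the probe position and the construction were not given, and no biological explanation was tested.

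A signal also appeared in probes outside every comparison: 14 of the 60 probes whose names start with EX were brighter than the median gene probe. The probe EX053 read 0.46, −3.84, −2.35 and −1.93 on arrays 1 to 4.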

How the results depend on the processing

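Leaving out high-background spots or the shifted grids of array 1, array weights, and loess within each grid for the lists and the relation were chosen only after the data were seen. The agar count of 38 genes moved to 18 with median centring, 2 with loess within each grid, 8 with scaling between arrays, 125 with an intensity trend and robust prior, 60 with the authors' values, 1 with array weights and 1 at an adjusted p of 0.01. It was 329 on its own arrays with a dye term, and limma called 0 there without one and 0 without background subtraction, with 589 and 999 genes at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 438. The share of agar calls that were higher moved from 26.3% to 38.9% with median centring, 37.5% with scaling, 41.7% with the authors' values, 44.7% on its own arrays with a dye term and 45.7% without array 6, and to 0% of 2 calls with loess within each grid. The spo0A count of 197 moved to 602 with scaling, 328 with the trend and robust prior, 673 with the authors' values, 361 without high-background spots, 329 without the shifted grids, 356 with array weights and 13 at an adjusted p of 0.01. On its own arrays it was 1160 with and 1134 without a dye term, and 4 to 419 with 1 array left out, 4 of them without array 5 and 4 without array 7. All 197 kept their sign in every alternative, the authors' values covering 196 of them, and 35 to 38 of the agar calls did. The agar lists past the test moved from 15 to 0 with an estimated correlation, 3 with fry and 9 with the authors' values, and to 6 to 16 with 1 array left out, 6 without array 6. The spo0A lists moved from 11 to 0 and 4 with the first 2 of these. The relation of the 2 comparisons moved from −0.254 to −0.384 without the shifted grids, and was negative in each of the 12 alternatives run for it. Median centring and the background, scaling, filter, trend and weight settings were not run for it. The agar ratio of yqxG turned to −0.03 with loess within each grid. The cause was not tested for any of these changes. With the authors' values the spo0A comparison lost arginine catabolism and the citric acid cycle (adjusted p = 0.28 and 0.32) and gained purine synthesis and PBSX (adjusted p = 0.0036 and 0.021). The agar comparison then lost the matrix exopolysaccharide, autolysin, ribosomal, branched-chain, arginine synthesis, glycolysis and citric acid cycle lists (adjusted p = 0.051 to 0.28) and gained PBSX (0.048). Loess within each grid ended the agar calls of ribosomal proteins, the citric acid cycle and acetoin use (adjusted p = 0.37, 0.11 and 0.17) and the spo0A calls of arginine catabolism, pyrimidine synthesis and the citric acid cycle (0.052, 0.052 and 0.11). The spo0A purine list also passed with median centring (0.021) and without the shifted grids (0.048). Keeping spots marked bad was not run, as they hold no intensity, and a median of duplicate spots is the mean of 2 spots and changes nothing. Low signal over background on arrays 3, 6 and 7 limits the values of dim genes. Arrays were not paired across the comparisons. The replicate numbers only count the arrays of the series, so they cannot show whether pairs existed. The slide numbers in the sample titles were not used as a batch. They are consecutive for arrays 2 and 3, and again for arrays 5, 6, 7 and 1 in that order. What the numbers stand for was not given, and a batch effect was not tested.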

Other observations

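The tests in this part were chosen only after the result was seen, except those of other sign patterns, which were planned. The gene lists of the next 2 paragraphs were also picked after the gene values were seen, with members listed from general knowledge and not checked against a source, so their p-values are not independent evidence.

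Members of the regulon of SigW, the sigma factor of cell envelope stress, were among the genes higher in RNA labelled spo0A. Of 33 measured members 16 were past the threshold, all higher, and 30 had ratios above 0 (median 0.83, camera p = 7.1e-22, and p = 0.0074 with an estimated correlation). In the agar comparison the median over 34 members was −0.21 and the list did not pass camera.

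Genes of the cytochrome bc complex and caa3 oxidase, of the respiratory chain, were among those lower in RNA labelled spo0A. Of 11 members 7 were past the threshold and all 11 ratios were below 0 (median −1.10, camera p = 7.1e-12, and p = 0.026 with an estimated correlation). On soft agar their median was −0.29 (camera p = 0.013, and p = 0.28 with an estimated correlation). The 4 measured riboflavin synthesis genes were all higher in RNA labelled spo0A (median 1.72, camera p = 1.5e-06, and p = 0.061 with an estimated correlation), with a median of 0.12 on soft agar (camera p = 0.49).

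The 2 comparisons opposed each other on balance across genes, although in the separate fits 45 genes were lower in both, against 25.9 for independent lists. That count rests on array 1, which had no residual in its separate fit. In the fit of all 7 arrays 0 genes were lower in both, against 0.574. Dye bias was argued against, since all 7 pairs of arrays of the same dye orientation correlated below 0, the highest at −0.08. Shared wild type RNA with no effect gave a simulated covariance of −0.0319, and the observed −0.0984 was further from 0. By correlation the order was the other way, with a simulated r of −0.352 (−0.396 to −0.295) and an observed r of −0.254. The simulation gave every array equal noise, which the real arrays did not have, so neither simulated value is a limit. Shared RNA could therefore be part of the pattern and stays open, as its use was not given. Higher Spo0A activity on soft agar is a hypothesis that stays open: abrB, which it would lower, stood at 0.45 ± 0.22 and did not pass the threshold. Of the processes that Spo0A starts, early sporulation leaned lower on soft agar (list median −0.54) and the eps operon higher (list median 0.24). Neither list passed camera with an estimated correlation (adjusted p = 0.55 each).

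Turning the sign of some arrays gives 8 patterns for the agar arrays and 4 for the spo0A arrays, too few for a share under 0.05. For the agar genes 1 of 8 patterns gave as many calls as the real one (38, highest other 0), and for the spo0A genes 1 of 4 (197, highest other 170, with array 6 turned). Beside the shared dye term, that other pattern is a Cy5 over Cy3 difference of arrays 5 to 7 alone. The model assumed that there was none. The unbalanced dye orientations also put part of the strain difference into that pattern. Whether the 170 calls break the assumption of 1 shared dye effect could therefore not be told. For the lists the real pattern gave 15 in the agar comparison, and 2 of 8 patterns gave as many. The other, also 15, had arrays 2 to 4 turned against array 1. Beside the shared dye term this is a Cy5 over Cy3 difference of arrays 1 to 4 alone, with part of the agar difference in it. In the spo0A comparison 1 of 4 patterns gave as many lists (11, highest other 5).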
